A study of Mus musculus with 12 samples.

How the data were processed

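Bulk poly(A) RNA sequencing was done on mouse bone marrow mesenchymal stem cells (BMSCs) in osteogenic medium, with 6 libraries from cultures that received α-asarone and 6 from cultures that did not. The sample labels spell the agent α-Asaronel, which is read here as α-asarone. Per the labels' protocols, cells were grown in DMEM with antibiotics (penicillin-streptomycin at 1%) and fetal bovine serum at 15%, and the osteogenic medium added 100 nM dexamethasone, 10 mM β-glycerophosphate and 50 µM ascorbic acid. Total RNA had integrity numbers above 7.0, about 10 µg entered poly(A) selection and fragmentation, and the mean insert was 300 bp, give or take 50 bp, per the labels' protocols. The dose of α-asarone, the time of exposure and whether the libraries kept strand are not given in the sources used here. The labels call the 6 libraries of a group biological replicates without saying whether they came from different animals or cultures, so p-values measure the spread between these libraries.

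The authors deposited 1 table with a TPM value (transcripts scaled to a fixed total per library) and an estimated count per gene and library, per the file headers. The estimated counts as deposited have 2 decimals, and 7.45% to 9.57% of the values of a library are not whole, which is what sharing reads between genes or transcripts gives. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the quantifier and their versions are not given in the sources used here. The table analysed here held 658 genes, those with the lowest Ensembl identifiers, and the TPM of these genes summed to 5.36% to 5.67% of the total to which TPM is scaled. It is therefore part of each library's transcriptome, and the totals below are not library depths. Genes outside it, Dmp1 among them, were not analysed here. All 658 identifiers matched GENCODE release M21 on GRCm38, from which coordinates were taken, and all are protein-coding genes.

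The design fixed before the data were examined was limma on log2(TPM + 1). It put edgeR's quasi-likelihood test in its place if raw counts were found. The file held estimated counts, which are not raw counts. The main test was nevertheless edgeR's (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on estimated counts rounded to whole numbers. It used TMM factors (0.976 to 1.03) and no covariate. That choice departs from the wording of the fixed design. Genes with a TPM of at least 1 in at least 6 libraries were tested, which left 512 of the 658. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are α-asarone minus control, with standard errors (SE) from the same fit, and confidence intervals are 95%. TPM values are means ± SD of 6 libraries. Pparg was also compared by an exact 2-sided permutation test of log2(TPM + 1) over the 924 arrangements of the libraries.

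Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Of 39 lists fixed before the data were examined, with 806 genes in all, 55 genes were in the table, 47 were tested and 8 lists had at least 3 tested genes. Terms of the deposited gene annotation with at least 5 tested genes, 564 in number, were tested in the same way. The names in the text follow a rule fixed beforehand. They are Dmp1 and Pparg, the 10 largest rises and 10 largest falls among called genes with a mean TPM of at least 5 in 1 group and no overlap between the groups' values, and, for each list, up to 4 called members with the largest change or, where none was called, up to 2 with the highest TPM. Clone-like names and pseudogenes were passed over. Apoe, Dlx3, Ltbp2, Lamb1, Fgf23, Sost, Cd79a, Cd3g, Vpreb3, Vwf, Esam and Ngfr fall outside this rule and were chosen after their values were seen, as were 3 added lists and their members.

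Total estimated counts over the 658 genes ranged from 843593 to 1224255 per library. Replicates were compared pair by pair within each group. The chi-square per degree of freedom over genes was 2.27 to 11.9 in the 30 pairs, above the sampling noise, so no library was counted as a copy of another. On simulated counts for the α-asarone and control comparison over 512 genes, the main test recovered 68% of genes changed 1.1-fold, 92% at 1.25-fold, 94% at 1.5-fold and 100% at 2-fold, and 2.21% of its calls were false. Reads can be shared with overlapping genes. Of the 50 genes with values that the rule names, 25 overlap another annotated gene, 10 of them on the same strand, and 7 have counts that are not whole in some library. Values of these genes are less certain than the rest.

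The alternatives fixed beforehand were other filters, median-ratio and quantile scaling, limma on log2(TPM + 0.1), log2(TPM + 5) and without a variance trend, library weights, a Mann-Whitney test, the replicate number as a block, and each library left out in turn. Limma on log2(TPM + 1), the test of the fixed design, was run as an alternative to edgeR. Alternatives chosen after seeing the data were DESeq2 1.42.0, library sizes taken from the ratio of count to TPM, table totals without factors, leaving out Apoe, and keeping only genes with whole counts.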

Results

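The transcriptomes of mouse BMSCs, the plastic-adherent stromal cells of bone marrow that can form bone, fat and cartilage cells, were compared after osteogenic induction with or without α-asarone, a phenylpropanoid found in the volatile oil of Acorus plants. Each group had 6 libraries. The table held 658 genes, and the total estimated counts over them were 1025290 ± 125897 (SD, n = 6) with α-asarone and 1080160 ± 121063 (SD, n = 6) in controls. Between 575 and 589 of these genes had at least 1 count in a library. Apoe, which encodes the lipid carrier apolipoprotein E, alone took 19.6% to 23.0% of the counts. The series title names 2 genes, Dmp1, a matrix phosphoprotein gene of osteocytes, and Pparg, the nuclear receptor gene of adipocyte differentiation. Dmp1 was not analysed here.

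With α-asarone, the largest rises were of Ramp2, Angptl4, Egfl6 and Meox1, and the largest falls were of Cnn1 and Acp5. Ramp2, which encodes a partner of the calcitonin receptor-like receptor, was 3.04-fold higher. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, was 2.71-fold higher, and Egfl6, a secreted matrix protein gene, was 2.51-fold higher. Cnn1, the gene of the actin-binding protein calponin 1, was 3.26-fold lower, and Acp5, the gene of tartrate-resistant acid phosphatase, was 2.20-fold lower. Of the 512 genes tested, 155 (30.3%) changed by edgeR's quasi-likelihood test, 66 higher and 89 lower, and these 6 genes were the ones that changed at least 2-fold. The typical change was small, with a median absolute log2 fold change of 0.20 among the 155 genes and 97 of them under 0.25. In 73 genes (14.3%, against 0.216% by chance) the values of the groups did not overlap. The first principal component carried 46.5% of the variance and separated the groups. Limma on log2(TPM + 1), the test of the fixed design, called 117 genes, 46 higher and 71 lower. Without the filter on low TPM 16 genes changed at least 2-fold. With table totals in place of TMM factors, a setting chosen after seeing the data, 127 genes were higher and 62 lower, so that 67.2% of calls were rises against 42.6% in the setting above.

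**Figure D1:**
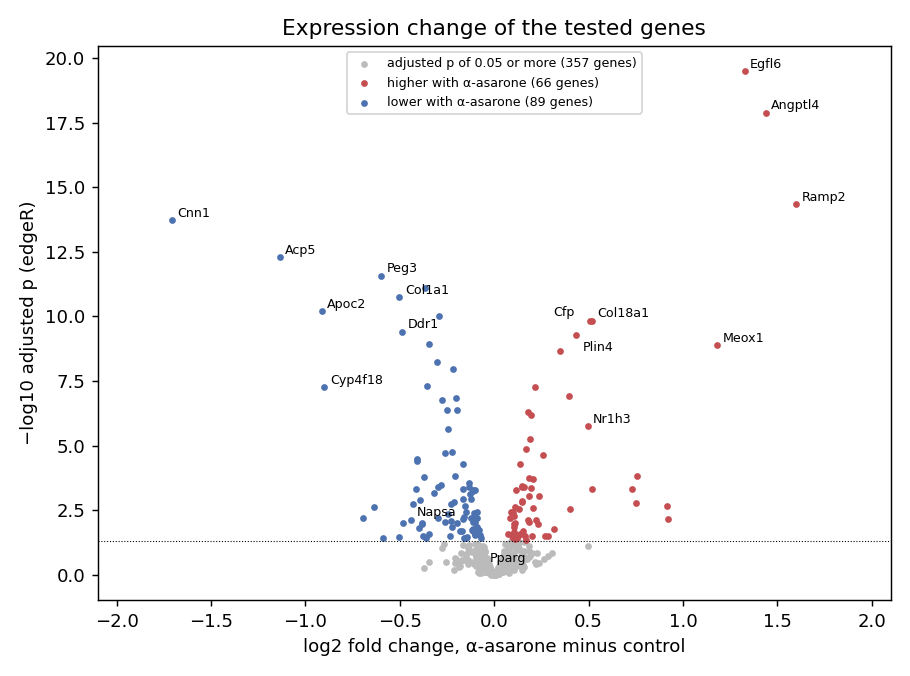
Each point is 1 of the 512 tested genes, with the log2 fold change (α-asarone minus control, 6 libraries each) on the x axis and −log10 of edgeR's adjusted p on the y axis, where the dotted line marks an adjusted p of 0.05. The 66 genes called higher are red and the 89 called lower are blue, Egfl6, Angptl4, Ramp2 and Meox1 lie above a log2 fold change of 1, Cnn1 and Acp5 lie below −1, and Pparg lies among the grey points.

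Pparg itself (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399, plus strand, GRCm38) did not differ beyond the spread between libraries. Its level was 40.2 ± 3.26 TPM (SD, n = 6) with α-asarone and 41.7 ± 1.97 TPM (SD, n = 6) in controls. The log2 fold change was −0.05 ± 0.05 (SE, edgeR adjusted p = 0.43), with a 95% confidence interval from −10.0% to 3.29%. The exact 2-sided permutation p was 0.327. An RNA of the opposite strand, Gm44079, overlaps the gene.

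Genes of the adipocyte and PPARG-target list were higher with α-asarone. Of its 6 tested members 4 rose and none fell, and the same 4 passed when adjusted over the list alone. Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830) went from 11.8 ± 0.963 to 32.0 ± 1.93 TPM (log2 fold change 1.44 ± 0.06 SE, edgeR adjusted p = 1.31e-18). Plin4, the gene of a lipid droplet coat protein, went from 11.9 ± 0.505 to 16.1 ± 0.851 TPM (log2 fold change 0.43 ± 0.04). Lipe, which encodes hormone-sensitive lipase, went from 15.4 ± 0.95 to 20.9 ± 1.12 TPM (log2 fold change 0.40 ± 0.05). Cd36, which encodes a fatty acid transporter and scavenger receptor, had 308 ± 22.7 TPM in controls and 366 ± 38.8 TPM with α-asarone (log2 fold change 0.24 ± 0.05, edgeR adjusted p = 8.4e-04). Pparg and Apoe did not pass. Apoe had 19102 ± 998 TPM in controls and 18857 ± 865 TPM with α-asarone. The list as a set had a median log2 fold change of 0.32 and a camera adjusted p of 5.8e-06, and adjusted p = 0.0049 with an estimated correlation. That set call rested on Angptl4, since without it the adjusted p was 0.081, and 0.30 with an estimated correlation. Angptl4 was also the 1 tested gene of the glucocorticoid response list, and the medium of both groups held dexamethasone. The Mann-Whitney test ended the call of Cd36, with an adjusted p of 0.067.

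**Figure D2:**
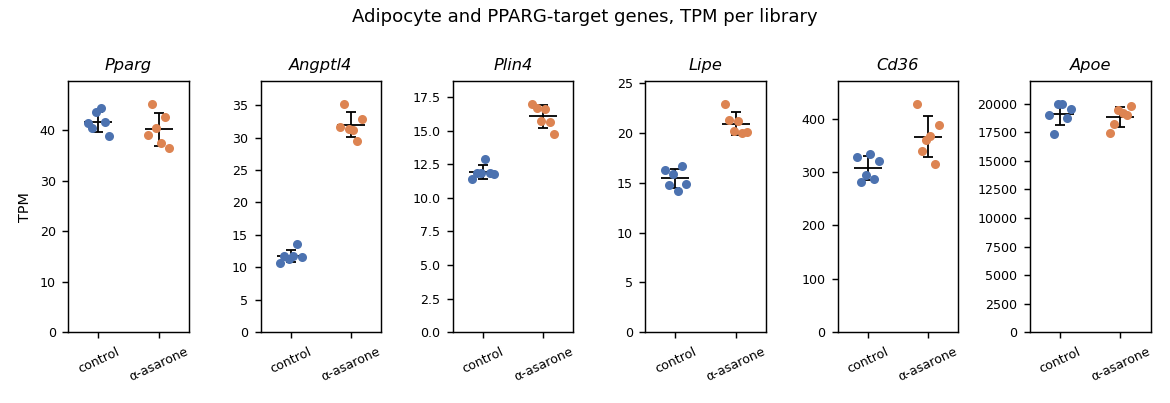
TPM on the y axis of the 6 tested genes of the adipocyte and PPARG-target list, with 1 point per library, control in blue and α-asarone in orange, and black bars for the mean ± SD of 6 libraries. Angptl4, Plin4 and Lipe have no overlap between the groups, Cd36 overlaps in part but passed the test, and Pparg and Apoe did not pass.

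In the fixed list of Pparg and other nuclear receptor genes, Nr1h3, which encodes the oxysterol receptor LXRα, rose from 14.04 ± 1.63 to 19.7 ± 0.775 TPM (log2 fold change 0.50 ± 0.07, edgeR adjusted p = 1.76e-06). Ppard, at 24.3 ± 1.86 TPM against 25.8 ± 1.89 TPM in controls, did not pass over all genes (log2 fold change −0.11, adjusted p = 0.12), nor did Pparg. The list had 1 of 3 tested genes higher, a median log2 fold change of −0.05, a mean of 0.11 and a camera adjusted p of 0.75 toward higher values, so that median and test differed in sign. Of 564 terms of the deposited annotation, 3 passed, all toward higher values. They were basement membrane, with Egfl6, Col18a1 and Lamb1 higher among 5 genes (adjusted p = 1.7e-04), the PPAR signaling pathway, with Angptl4, Plin4, Nr1h3 and Cd36 higher among 6 genes (adjusted p = 8.1e-04), and negative regulation of endothelial cell apoptotic process, with 2 genes higher, 2 lower and a median just under 0 (adjusted p = 0.025). With an estimated correlation none of the 3 passed, at adjusted p = 0.20, adjusted p = 0.28 and adjusted p = 0.53 in that order.

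Bone and matrix genes moved in different directions. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), the gene of the main collagen chain of bone, fell from 1852 ± 141 to 1304 ± 78.8 TPM (log2 fold change −0.50 ± 0.04, edgeR adjusted p = 1.79e-11), while Col18a1, a basement membrane collagen gene, rose from 35.1 ± 2.56 to 49.7 ± 4.32 TPM and Col6a1 rose from 641 ± 8.55 to 724 ± 18.3 TPM. Under quantile scaling the change of Col6a1, at 0.05 (adjusted p = 0.22), did not pass. The change of Col1a1 was 0 under that scaling by construction, since the gene ranks the same in every library, so this is no evidence against its fall. The 3 tested collagen genes thus had 2 rises and 1 fall, also when adjusted over the list alone, and as a set did not pass (camera adjusted p = 0.75). Of 2 tested genes of collagen processing, Fkbp10, which encodes a collagen chaperone of the endoplasmic reticulum, fell by 0.37 on the log2 scale to 156 ± 6.32 TPM, and the lysyl oxidase family gene Loxl3 rose by 0.22 to 235 ± 6.23 TPM. Counts of Loxl3 were not whole in any library and those of Fkbp10 in 66.7% of libraries. None of 3 matrix protease and inhibitor genes passed with edgeR, nor did any before adjustment (camera adjusted p = 0.83). Timp1 had 786 ± 72.1 TPM with α-asarone against 809 ± 37.1 TPM, and Mmp14 359 ± 8.01 TPM against 357 ± 10.1 TPM. Dlx3, the other tested gene of the osteoblast list besides Col1a1, was at 1.97 ± 0.503 TPM against 1.65 ± 0.248 TPM and did not pass. The osteocyte genes Fgf23 and Sost were below the filter, Fgf23 at 0.223 ± 0.0957 TPM with α-asarone and 0.164 ± 0.128 TPM in controls, and Sost listed at 0 in every library.

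**Figure D3:**
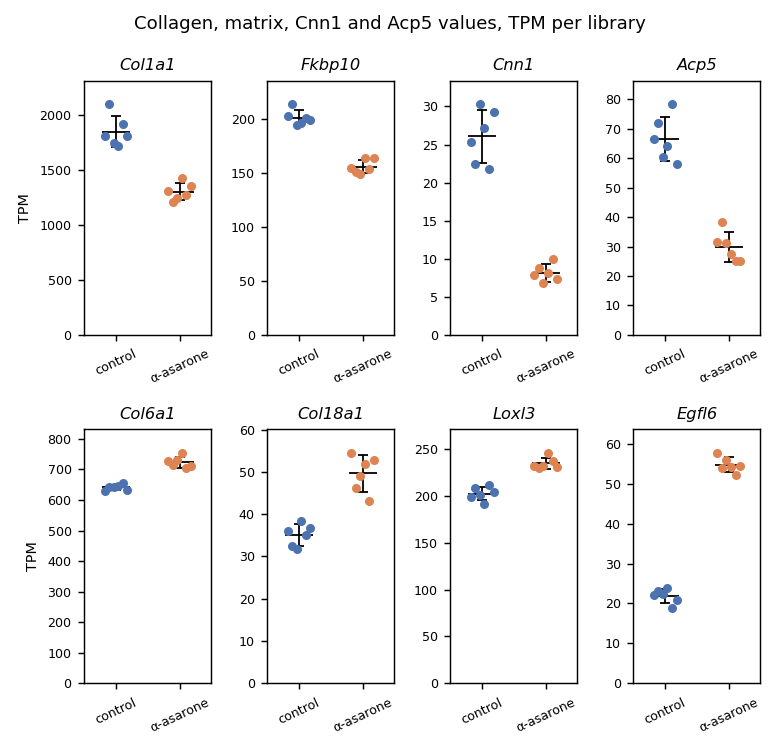
TPM on the y axis of 8 genes in each library, control in blue and α-asarone in orange, with black bars for the mean ± SD of 6 libraries. Col1a1, Fkbp10, Cnn1 and Acp5 are lower with α-asarone and Col6a1, Col18a1, Loxl3 and Egfl6 are higher, with no overlap between the groups in any of the 8. Col6a1 did not pass under quantile scaling, and Col1a1 could not pass under it, since it ranks the same in every library.

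Markers of other lineages that a marrow culture could hold were each represented by 1 tested gene or none. Cnn1 (ENSMUSG00000001349, chromosome 9, 22099216 to 22109630), of the smooth muscle and contractile list, fell from 26.1 ± 3.50 to 8.14 ± 1.13 TPM (log2 fold change −1.71 ± 0.10, edgeR adjusted p = 1.91e-14). Acp5 (ENSMUSG00000001348, chromosome 9, 22126727 to 22135711), of the osteoclast list, fell from 66.6 ± 7.57 to 29.8 ± 5.07 TPM (log2 fold change −1.14 ± 0.08, adjusted p = 5.21e-13). Spi1, which encodes the myeloid transcription factor PU.1, rose from 143 ± 5.13 to 163 ± 8.88 TPM, and Cfp, the gene of the complement regulator properdin, rose from 332 ± 23.1 to 469 ± 45.6 TPM. Sox9, of the chondrocyte list, fell by 0.26 on the log2 scale to 7.93 ± 0.615 TPM, a call lost with the Mann-Whitney test (adjusted p = 0.14), under quantile scaling (adjusted p = 0.095) and with limma on log2(TPM + 0.1) (adjusted p = 0.051). Col6a1 was the tested gene of the tendon list. Lymphocyte genes (Cd79a, Cd3g and Vpreb3) reached at most 0.099 TPM and the endothelial genes Vwf and Esam at most 1.33 TPM in any library. The neural list had only Ngfr below the filter, at 1.08 ± 0.247 TPM with α-asarone and 0.589 ± 0.183 TPM in controls.

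The other largest changes among genes that met the naming rule, with its TPM minimum and no overlap between the groups, lay outside these lists. Some called genes with larger changes than those below failed that rule and are not named here. Ramp2 (ENSMUSG00000001240, chromosome 11, 101246028 to 101259546) went from 11.8 ± 2.31 to 37.3 ± 2.98 TPM (log2 fold change 1.60 ± 0.09, edgeR adjusted p = 4.64e-15), with counts that were not whole in 75% of libraries and an overlap with Vps25 on the same strand. Egfl6 (ENSMUSG00000000402, chromosome X, 166523007 to 166585720) went from 21.9 ± 1.85 to 54.8 ± 1.92 TPM (log2 fold change 1.33 ± 0.05), and the homeobox gene Meox1 from 3.31 ± 0.55 to 7.59 ± 0.914 TPM (log2 fold change 1.18 ± 0.12). Mmd rose by 0.35 on the log2 scale, with counts not whole in 83.3% of libraries. Among the falls, Apoc2, which encodes an activator of lipoprotein lipase, went from 50.9 ± 2.53 to 27.0 ± 2.85 TPM with counts not whole in 66.7% of libraries. Cyp4f18 went from 8.53 ± 0.641 to 4.55 ± 0.585 TPM and the imprinted gene Peg3 from 24.4 ± 1.74 to 16.02 ± 1.04 TPM. Ddr1, a collagen receptor gene, fell by 0.49 on the log2 scale, Napsa by 0.44, the homeobox gene Hoxc6 by 0.41 and the costimulatory ligand gene Icosl by 0.41.

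All 4 tested immediate early genes passed, with Fosb (log2 fold change 0.73 ± 0.15) and Ier3 (0.22 ± 0.06) higher and Klf4 (−0.31 ± 0.03) and Klf6 (−0.11 ± 0.02) lower. The list did not pass as a set (camera adjusted p = 0.75 toward lower values, although its median of 0.06 and mean of 0.13 were positive), and the Mann-Whitney test ended the call of Ier3 (adjusted p = 0.063). Tgfb1 rose from 164 ± 3.24 to 183 ± 6.11 TPM, while Ltbp2, the other tested gene of the BMP and TGF-β list, did not pass. The Wnt genes Axin2 (log2 fold change 0.04 ± 0.09) and Tcf7 (−0.14 ± 0.12) did not pass, nor did Bax and Bbc3 of the p53 list, Mx1, Nqo1 or Hk2. Calr, an endoplasmic reticulum chaperone gene, fell by 0.09 and Cyp51, of sterol synthesis, by 0.12 on the log2 scale. Calr did not pass with table totals (adjusted p = 0.11) or under quantile scaling (adjusted p = 0.42), nor Cyp51 under the latter (adjusted p = 0.073). None of 4 nuclear genes of oxidative phosphorylation (Atp5d −0.01, Cox5a 0.01), 3 ribosomal protein genes (Rpl13 0.02, Rpl8 0.06) or 3 cell cycle genes (Mcm2 0.07, Ccne1 0.19, all log2 fold changes) passed with edgeR, and their camera adjusted p values were 0.98, 0.75 and 0.75. Before adjustment 2 of these 10 genes, Rpl8 and Ccne1, lay under 0.05 with edgeR. Ccne1 passed in every limma fit run, with adjusted p values from 0.015 to 0.030. Rpl8 passed with edgeR under median-ratio scaling (adjusted p = 0.036) and without the filter (adjusted p = 0.048), with the Mann-Whitney test (adjusted p = 0.043) and with DESeq2 (adjusted p = 0.012), among other settings. Adjusted over the list alone, counts of calls were the same for every fixed list except that of fatty acid oxidation, whose only tested gene was Ppard. Genes of 9 of the 39 fixed lists, among them mesenchymal surface markers, heat shock and inflammatory cytokine genes, were not analysed here.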

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

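In 104 groups of 6 libraries, the highest or lowest value was compared with its nearest neighbour. Of these groups 3 had a value set apart by more than Dixon's critical value for 6 values, where chance alone gives about 5.2. Plin4 reached 12.9 TPM in control replicate 4, with the other controls between 11.4 and 11.9 TPM, and this value still lay below every α-asarone library. Klf6 was 123 TPM in α-asarone replicate 6, with the others of its group between 127 and 130 TPM. The total estimated count of control replicate 2 was 843593, with the other controls between 1068545 and 1173845. Without that library 152 genes changed.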

How the results depend on the processing

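Alternatives chosen after seeing the data were DESeq2, library sizes from the ratio of count to TPM, table totals, leaving out Apoe, genes with whole counts, and the adipocyte list without Angptl4. Limma on log2(TPM + 1) was the test of the fixed design, run here as an alternative to edgeR. The number of genes changed stayed between 104 (Mann-Whitney test) and 189 (table totals) against 155, with 160 by DESeq2, 117 by limma on log2(TPM + 1), 153 with library sizes from the ratio of count to TPM and 138 to 152 with each library left out. Genes changed at least 2-fold numbered 16 without the filter, which let in genes of low TPM, and 6 to 8 with each library left out, against 6. Table totals raised the higher calls from 66 to 127, with a shift of 0.043 in the median of all genes. Pparg did not pass under any alternative, at log2 fold changes from −0.088 to −0.0093. Same-numbered libraries of the groups had correlations from −0.003 to 0.128, and 2 of 6 correlated best with their own number. No clear pairing by number was seen, although 6 pairs are too few to rule it out. With the replicate block 168 genes changed, 6 of them at least 2-fold, and the log2 fold change of Pparg was −0.054. The adipocyte and PPARG-target list had an adjusted p of 0.0812652 without Angptl4 and 0.30 with an estimated correlation as well. Fry, which tests whether a list's genes move on balance one way without comparing them with other genes, passed the adipocyte and PPARG-target list (adjusted p = 1.7e-07) and the cell cycle (adjusted p = 0.041), collagen (0.042), immediate early (0.036) and nuclear receptor (0.042) lists. Over the other 49 named genes no call reversed, and 1334 of 1362 alternative values kept the call or the absence of one. In 10, for 7 genes, a call was lost, and Col1a1 under quantile scaling is one by construction, since it ranks the same in every library. In 18 a call was gained, 8 for Ccne1, 9 for Rpl8, the replicate block among them (adjusted p = 0.049), and 1 for Ppard. Leaving out 1 library sufficed, control replicate 4 for Ccne1 (adjusted p = 0.028), α-asarone replicate 3 for Ppard (adjusted p = 0.037) and control replicate 6 for Rpl8 (adjusted p = 0.049). The cause of the other changed calls was not tested. The SE of the log2 fold change was 0.15 for Fosb, with a mean count of 40, and 0.02 for Col6a1, with a mean count of 24430.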

Other observations

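Tests of the adipocyte, matrix, leukocyte and neighbouring gene patterns below, and the leukocyte, stromal matrix and Hox lists, were chosen after the result was seen. Only the comparison with other splits of the libraries was planned.

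Genes of blood cells were abundant in both groups. Of 15 leukocyte genes, 2 of which also belong to the fixed macrophage or complement lists, 11 reached at least 10 TPM in every library. Itgb2, the leukocyte integrin β2 gene, lay between 263 and 300 TPM, Spi1 between 136 and 177 TPM, Cfp between 307 and 550 TPM and the lectin gene Clec10a between 97.0 and 129 TPM. With α-asarone 4 of the 15 rose (Cfp, Spi1, Ccl3 and Il7r) and 5 fell (Itgb2, Cd52, Il16, Def6 and Itgb7), and the list did not pass as a set (camera adjusted p = 0.67 toward higher values, with a median of −0.04 and a mean of 0.02). Adjusted over the list alone, 6 rose and 5 fell.

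Hox genes, which encode homeobox factors of body position, were lower in part. Of 6 tested Hox genes 4 fell and none rose. Hoxc13 fell by 0.43, Hoxc6 by 0.41, Hoxc11 by 0.38 and Hoxa10 by 0.21 on the log2 scale, while Hoxa4 and Hoxc8 did not pass. The list did not pass with camera (adjusted p = 0.17, and adjusted p = 0.24 with an estimated correlation) and passed with fry (adjusted p = 5.5e-06).

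The counts of changed genes were higher than those that other splits of the libraries gave. Of 100 splits drawn from the 462 possible, the real one included, 1 gave as many as 155 genes, the real one, and the highest other gave 26. For changes of at least 2-fold 1 split gave as many as 6 genes, and the highest other gave 1. Splits that mix the groups take the difference between the groups into their spread, which lowers their counts. The comparison cannot tell α-asarone from another difference between the groups, such as one of animals or cultures.

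The higher adipocyte and PPARG-target genes beside a Pparg level that did not pass form the first pattern. A larger share of all leukocytes alike with α-asarone would raise their genes together, but of the 15 leukocyte genes 4 rose and 5 fell. That list was chosen after its values were seen and mixes genes of several leukocyte types. Since Spi1 and Cfp rose, it cannot tell whether the share of some leukocyte type grew. A library-scale offset is argued against by the smallest log2 fold change of Angptl4, Plin4, Lipe and Cd36 over the scalings, which was 0.24. The set test is carried by Angptl4, since the adjusted p without it was 0.081. A treatment effect on these genes, or a change of state within 1 cell type, may also remain as a hypothesis that was not tested further.

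The lower Col1a1, Fkbp10 and Cnn1 form the second pattern. Fewer stromal cells in the treated cultures would lower their matrix genes together. Of 13 stromal matrix genes 4 rose (Col18a1, Loxl3, Col6a1 and Lamb1) and 3 fell (Col1a1, Fkbp10 and Ltbp1). The list did not pass (camera adjusted p = 0.67 toward lower values, with a median near 0). It was chosen after most of these changes were seen and holds Col1a1 and Fkbp10 themselves. It therefore shows that these genes did not fall together but cannot decide whether stromal cells were fewer. A library-scale offset is argued against by the log2 fold change of Col1a1, which came no nearer to 0 than −0.46 over the scalings of the libraries, quantile scaling aside. A change specific to some matrix genes may also remain, as a hypothesis.

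The high leukocyte genes form the third pattern. Myeloid cells in the cultures are a candidate source, since 11 of the 15 leukocyte genes reached 10 TPM in every library while the lymphocyte genes stayed at or under 0.099 TPM. The labels mention no sort that would remove such cells, and no biological explanation of their presence was tested. Acp5 and Spi1 moved in opposite directions, and the cell type in which either changed was not tested.

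Cnn1 and Acp5, with the largest falls, lie 17097 bp apart on chromosome 9, which raised the hypothesis that neighbouring genes changed alike. Over 329 pairs of tested genes within 100 kb that do not overlap, the correlation of log2 fold changes, taken across genes, which are not independent replicates, was 0.17 (1-sided permutation p = 0.0032, adjusted p = 0.0097 over the 3 versions run). On ranks it was 0.09 (permutation p = 0.048, adjusted p = 0.072), and without the Cnn1 and Acp5 pair that raised the question it was 0.07 (permutation p = 0.07565, adjusted p = 0.076). Of 35 pairs with both genes called, 20 moved in the same direction. The version on ranks was first set as the deciding one. After its result was seen, the version without the Cnn1 and Acp5 pair was made the deciding one instead. The hypothesis therefore rests largely on 1 pair and stays open.

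The ratio of count to TPM, which would move if a gene's expressed transcripts changed in length, differed between groups in 0 of 436 genes by limma on the log2 ratio, and in 24 at an unadjusted p under 0.05.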
